A study of Mus musculus with 10 samples.

How the data were processed

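Reduced representation bisulfite sequencing libraries were made from testis DNA of F2 mice, 5 labelled control and 5 labelled arsenic. Per the labels' protocols, DNA was extracted with phenol and chloroform, purified with a column kit and made into libraries with the NEBNext Ultra II kit. Trim Galore 0.6.5, Bismark 0.22.3 and methylKit 1.22.0, and the genome build mm10, are named in the submitters' processing notes; their settings are not given in the sources used here. Per the file headers, the deposited table is of the kind methylKit writes when it unites libraries, with read counts per cytosine and library: the count of all reads, the count read as methylated and the count read as unmethylated. These counts were not normalised, and the first equalled the sum of the others at every cytosine. Each strand of a CpG had its own row: 581375 CpGs had both strands, and 1988759 cytosines lay on 1407384 CpGs. The lowest coverage in any library was 10, so the coverage minimum of 10 chosen for the analysis removed no cytosine.

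Depth sets the precision of a methylation level. Median coverage per cytosine was 27 reads in control library 4 and 29 in control libraries 2 and 5, the lowest of the set, and 40 in arsenic library 3, the highest. Reads carry no molecular identifiers, so limits from a count of 0 (3 counts of the total) cover counting error only. The labels do not say that libraries of a group came from separate animals, and p-values measure the spread between these libraries, which may be technical. Libraries were grouped by the group in their titles and numbered as there.

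The unit of analysis was the cytosine, the 1000 bp tile with at least 3 covered CpGs, or the end of a protein-coding gene. The gene table used was on the mouse assembly GRCm38.p6, the assembly behind mm10, and gives each gene's lower and higher coordinate without its strand, transcripts or exons. Promoters could therefore not be placed as planned. In their place, for each of 21896 protein-coding genes, the 1000 bp on each side of the gene end with more covered CpGs were used (the lower coordinate on a tie), a choice that does not use the groups. A window can thus lie at the 3' end of a gene. Windows of the maternally methylated imprinted regions reached 500 bp on each side of such an end. Those of the paternally methylated regions lay 1500 to 5000 bp upstream of H19, 10000 to 15000 bp upstream of Meg3 and 28000 to 32000 bp upstream of Rasgrf1. Meg3 had fewer than 3 covered CpGs. Of 161 gene symbols in the 10 lists, 161 were found in the gene table, 2 of them by an older name. Exons, introns and repeats were not analysed here, since they need an annotation or a genome sequence. The genomic classes were CpGs within 1 kb of either end of a protein-coding gene, other CpGs inside such genes, and the remainder.

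Mean methylation per library weighted each cytosine equally and was compared with a two-sided exact permutation test over 252 assignments of the labels, whose smallest p is 0.00794. Lists were compared in the same way on the mean over their measured members, those with at least 3 covered CpGs, with Benjamini-Hochberg (BH) adjustment over the 10 lists, and the genomic classes with adjustment over the 7 classes. If only 1 list or class reaches the smallest p, its adjusted p stays above 0.05, so a single one could not pass. Cytosines, tiles and gene ends were tested with a quasi-binomial logistic model of methylated out of all reads with a group term. Its Pearson dispersion was squeezed across features as in limma and not allowed under 1, the group was tested with an F test, and p was BH-adjusted over all features of a kind. A feature was called at an adjusted p under 0.05 and a difference of at least 10 percentage points in the read-weighted level. The levels given with an SD are means over libraries, so they can differ slightly from that difference. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1. The model was tested on simulated data with the real coverage, in which 100 features per size were changed by 10, 20 or 30 percentage points. Low levels were raised and high levels lowered, so losses from a low level were not simulated. Unchanged features had an unadjusted p under 0.05 in 6.68% of cytosines, 5.75% of tiles and 6.00% of gene ends, above the nominal 5%, and the calls included 0, 5 and 4 unchanged features in the 3 runs.

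The tests, gene lists and thresholds, and the rule for named features, were fixed before the data were examined, except the gene-end windows. The rule named up to 8 called tiles and gene ends in each direction. With fewer than 5 called of a kind, it named the 4 with the smallest p in each direction as features that did not pass; 1 gene end that this rule names is not reported here. It named the 3 members of each list with the smallest p, and all measured members of the imprinted lists. Other settings listed beforehand were a coverage of at least 20, a cap at the 99.9th coverage percentile, the dispersion of each feature alone, a binomial test with reads as replicates, limma on log2 ratios with 1 added to each count, and methylKit's default thresholds of 0.01 and 25 percentage points. Also tried were no minimum difference, the replicate number as a block, the mean of the maternally methylated regions as a covariate, 300 bp tiles, at least 5 CpGs, 500 bp windows, other weightings of the means, and each library left out in turn. A coverage minimum of 5, also listed, was not run, since the table starts at 10. Leaving out control libraries 4 and 5 together, summing the strands, and leaving Grb10 and Inpp5f out of the maternal list were added after seeing the data.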

Results

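DNA methylation was measured by reduced representation bisulfite sequencing, which enriches CpG-rich fragments with a restriction enzyme and reads unmethylated cytosines as thymines. The samples were testis DNA of F2 mice, from 5 control and 5 arsenic libraries. The labels give the generation and the group, and not which ancestor was treated or at what dose. The deposited table held methylated and unmethylated read counts at 1988759 CpG cytosines on 1407384 CpGs, each covered by at least 10 reads in each of the 10 libraries. Reads over these cytosines totalled 69771871 in control library 4 and 100355708 in arsenic library 3, the lowest and highest of the set. Median coverage per cytosine was 27 to 36 reads in the control libraries and 35 to 40 reads in the arsenic libraries. Control libraries 4 and 5 were fully methylated at 16.9% and 18.8% of cytosines, against 11.1% to 14.9% in the remaining 8 libraries. Pearson's r of methylation levels across cytosines, which are not independent replicates, was 0.948 to 0.968 between pairs of libraries. The first 2 principal components carried 14.5% and 12.8% of the variance, and each set 1 library apart (control 5 and control 4), not the groups.

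The first comparison addressed the mean methylation of testis DNA in the control and arsenic groups. Over all cytosines the level was 53.7% ± 0.447 (SD, n = 5) in control and 53.4% ± 0.241 (SD, n = 5) in arsenic. CpGs within 1 kb of either end of a protein-coding gene were the least methylated class, at 11.9% ± 0.680 in control and 11.4% ± 0.178 in arsenic. Gene bodies stood at 67.0% ± 0.422 and 66.9% ± 0.208, and intergenic CpGs at 67.1% ± 0.332 and 66.8% ± 0.361. On the X chromosome the level was 59.6% ± 0.216 in control and 59.2% ± 0.505 in arsenic, and on the Y chromosome 62.7% ± 0.640 and 62.0% ± 1.71. The arsenic mean was lower in all 7 classes, with differences of -0.145 to -0.646 percentage points. None of these differences exceeded the spread between libraries: the two-sided exact permutation test gave p = 0.214 for all cytosines (BH-adjusted p = 0.356) and p = 0.167 to 0.548 over the 7 classes. Near gene ends, control libraries 4 and 5 stood at 12.3% and 12.9%, and the other 8 libraries between 11.3% and 11.7%. Without these 2 libraries, a choice made after seeing the data, the difference over all cytosines changed sign, to 0.0320 percentage points.

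**Figure D1:**
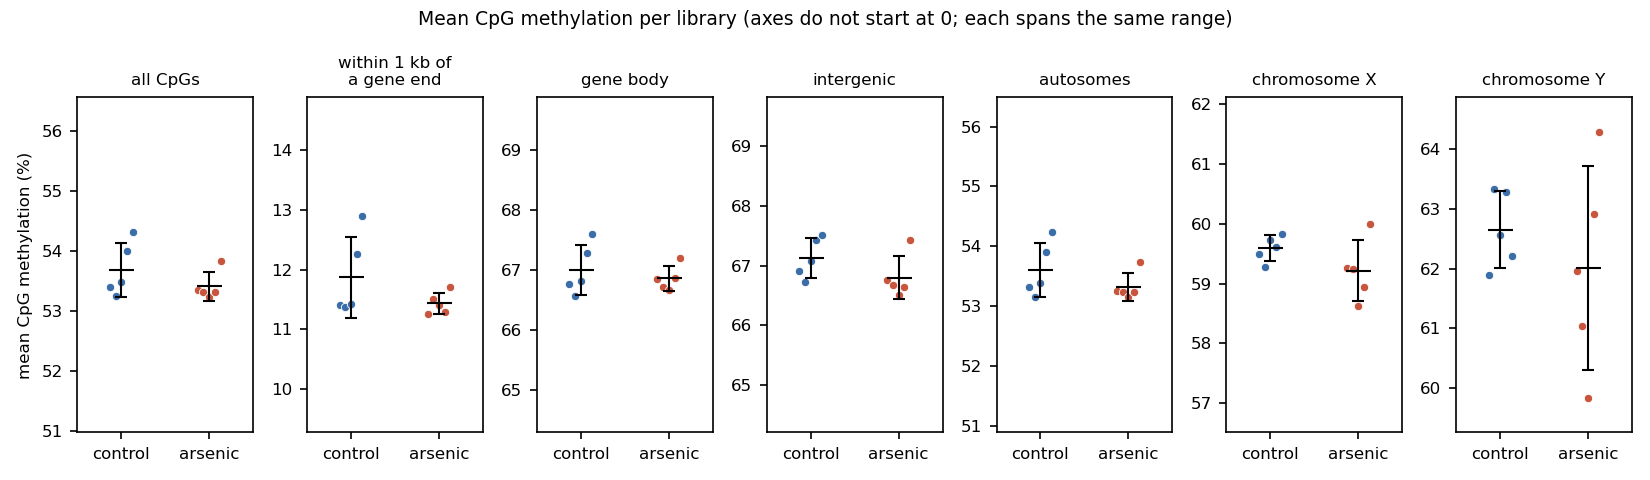
Mean CpG methylation in percent (vertical axes, each spanning the same range and not starting at 0) for the 5 control and 5 arsenic libraries in 7 genomic classes. Points are libraries and bars are the mean ± SD; near gene ends, 2 control points at 12.3% and 12.9% lie above the other 8 libraries.

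The second comparison asked which single cytosines differed between the groups. The quasi-binomial logistic model with Benjamini-Hochberg adjustment called 0 of 1988759 cytosines, with a lowest adjusted p of 0.662. An unadjusted p under 0.05 was found at 141458 cytosines, or 7.11%, of which 60945 were higher and 80513 lower in arsenic. Limma on log2 ratios of methylated to unmethylated reads also called 0. A binomial test that treats reads as replicates, and so leaves out the spread between libraries, called 82352 cytosines (35946 higher and 46406 lower in arsenic). The 5 control and 5 arsenic levels did not overlap at 0.528% of cytosines, where chance gives 0.794% if no levels are tied. Each library was fully unmethylated at 22.4% to 24.7% of cytosines. Ties lower the share that chance gives, so the observed share cannot be read as below chance. The quasi-binomial model was also run on simulated data of the same size and coverage. It recovered 0 of 100 cytosines changed by 10 percentage points, 3 of 100 changed by 20 and 9 of 100 changed by 30. Most differences of these sizes at single cytosines were thus not detectable with this coverage, number of libraries and number of tests. This holds where few cytosines change, and for low levels raised or high levels lowered, as in the simulation (100 per size). The minimum of 10 percentage points for a call also limits recovery of changes of 10.

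The third comparison asked the same of 1 kb tiles, in which the reads of neighbouring CpGs were summed. Of the tiles with the smallest p, those with the higher arsenic level lay in Xlr5c, a member of the X-linked lymphocyte-regulated gene family, near the homeobox gene Evx1, in the predicted gene Gm40620 and in Scara5, a ferritin receptor. Those with the lower arsenic level lay in Pik3c2a, a phosphoinositide kinase, in Nexn, an actin-binding protein of muscle, and in 2 neighbouring tiles of Gpr179, an orphan receptor of retinal bipolar cells. None of these passed the test. The Xlr5c tile (mm10, X chromosome, 73293001 to 73294000, 4 CpGs) was at 0% in every control library and at 29.7% ± 9.75 (SD, n = 5) in arsenic. The Gm40620 tile (chromosome 10, 29289001 to 29290000) stood at 64.0% ± 3.25 in control and 83.6% ± 5.78 in arsenic. The tile 1612 bp from Evx1 (chromosome 6, 52320001 to 52321000) stood at 81.7% ± 2.36 and 90.2% ± 1.62, and the Scara5 tile (chromosome 14, 65676001 to 65677000) at 79.6% ± 3.92 and 88.9% ± 0.627. In Gpr179, the tile at 97337001 to 97338000 on chromosome 11 stood at 32.9% ± 4.79 in control and 17.6% ± 3.23 in arsenic, and the next tile, to 97339000, at 27.2% ± 4.81 and 12.8% ± 1.49. The Pik3c2a tile (chromosome 7, 116443001 to 116444000) stood at 7.40% ± 1.32 and 1.06% ± 0.986, and the Nexn tile (chromosome 3, 152265001 to 152266000) at 4.84% ± 2.18 and 0.796% ± 0.331. In each of these 8 tiles the 5 control levels and the 5 arsenic levels did not overlap.

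The quasi-binomial model called 0 of 165978 tiles, and the adjusted p was 0.474 for 7 of the tiles just named and 0.575 for the Scara5 tile. An unadjusted p under 0.05 was found at 9631 tiles (5.80%), 4086 higher and 5545 lower in arsenic. Groups did not overlap at 0.832% of tiles, against 0.794% by chance without ties. Limma called 1 tile, that of Xlr5c, with an adjusted p of 0.00681. The binomial test on reads called 1986 tiles, 693 higher and 1293 lower. The Xlr5c tile rested on 40 to 104 read calls per library, the Gm40620 tile on 150 to 348, and the Pik3c2a tile on 1384 to 2751. The 4 CpGs of the Xlr5c tile lay between 73293011 and 73293042. In arsenic library 1 each had 26 reads, 6 of them methylated, and in control library 4 each had 10 reads. The same reads may thus be counted at each CpG, so these calls are not independent, while the model and limma count them separately. In simulated data the model recovered 12 of 100 tiles changed by 10 percentage points, 53 of 100 changed by 20 and 76 of 100 changed by 30. Few tiles changed in that simulation, and low levels were only raised.

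**Figure D2:**
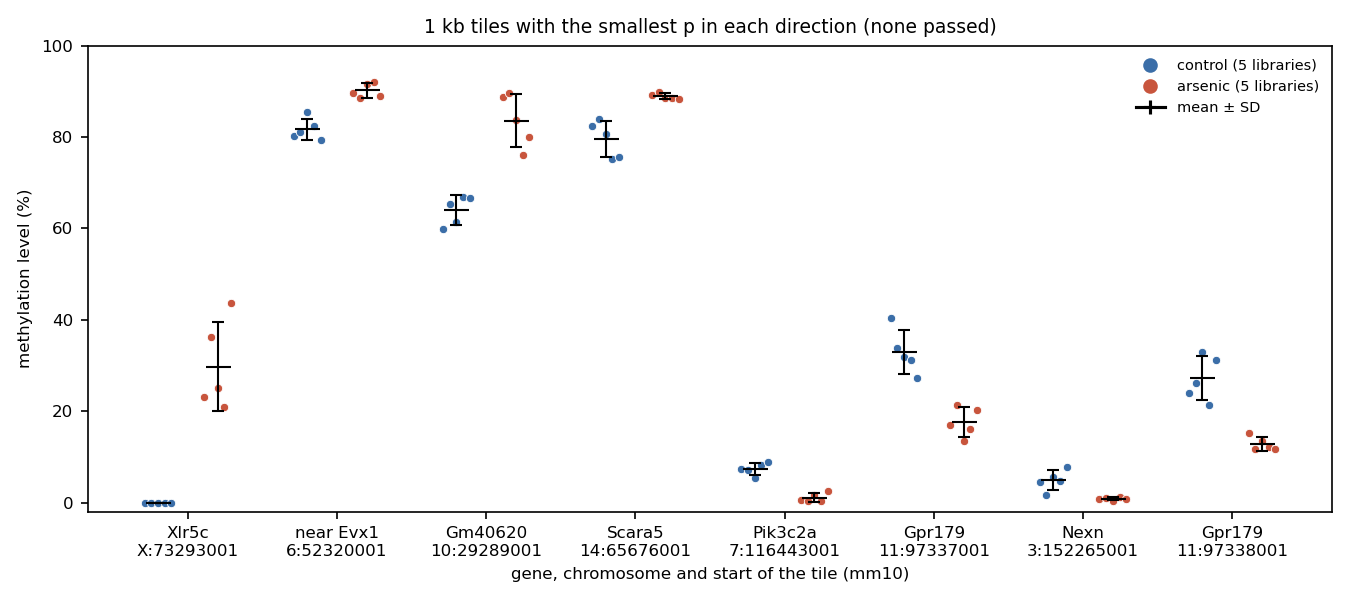
Methylation level in percent (vertical axis) of the 1 kb tiles with the smallest p, 4 higher and 4 lower in arsenic, in the 5 control and 5 arsenic libraries. Points are libraries and bars are the mean ± SD; the Xlr5c tile is at 0% in each control library and averages 29.7% in arsenic, and the named tiles did not pass the adjusted test.

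The fourth comparison took a window at 1 end of each protein-coding gene, the end with more covered CpGs, in place of the promoter. With the smallest p among windows lower in arsenic stood Pik3c2a, Ifngr2, a chain of the interferon gamma receptor, Kdm3a, a histone demethylase required for spermatid maturation, and Marveld1. These windows averaged 4.22% to 7.40% in control and 0.465% to 1.06% in arsenic; at Kdm3a control library 1, at 0.300%, lay within the arsenic levels. Ifngr2 (chromosome 16, 91546059 to 91548059) stood at 7.31% ± 3.39 (SD, n = 5) in control and 0.465% ± 0.406 in arsenic. Kdm3a (chromosome 6, 71631990 to 71633990) stood at 6.07% ± 3.70 and 0.469% ± 0.289, and Marveld1 (chromosome 19, 42146389 to 42148389) at 4.22% ± 1.13 and 0.785% ± 0.677. The Pik3c2a window held the same 45 CpGs as its tile and the same levels. Among windows higher in arsenic, Xlr5c (X chromosome, 73292863 to 73294863, 5 CpGs) stood at 0% in every control library and 30.5% ± 9.10 in arsenic. Exoc5, a subunit of the exocyst (chromosome 14, 49065667 to 49067667), stood at 0.201% ± 0.305 and 4.97% ± 4.29, and Fam167a (chromosome 14, 63435394 to 63437394) at 0.122% ± 0.137 and 2.22% ± 1.47. At Exoc5 arsenic libraries 1 and 3, at 0.539% and 0.371%, lay within the control levels.

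None of these gene ends passed: the quasi-binomial model called 0 of 14223, with adjusted p of 0.243 for Xlr5c and Pik3c2a, 0.385 for Ifngr2, 0.396 for Kdm3a and Marveld1, and 0.575 for Exoc5 and Fam167a. An unadjusted p under 0.05 was found at 909 gene ends (6.39%), of which 659 were lower and 250 higher in arsenic. Groups did not overlap at 0.942% of gene ends, against 0.794% by chance without ties. Limma called 1 gene end, Xlr5c, with an adjusted p of 0.00127, and the binomial test on reads called 74, 23 higher and 51 lower. Without control libraries 4 and 5 the count of calls stayed at 0, and 563 of 904 gene ends with an unadjusted p under 0.05 were lower. The Xlr5c levels rested on 10 to 24 reads per cytosine in the control libraries, and 0 of 10 reads in control library 4 allows a level of up to 30%, 0 of 24 in control library 5 up to 12.5%. With windows of 500 bp instead of 1000 bp on each side, the Marveld1 difference of -3.43 percentage points was -1.26. In simulated data the model recovered 21 of 100 gene ends changed by 10 percentage points, 80 of 100 changed by 20 and 91 of 100 changed by 30. Few gene ends changed there and low levels were only raised, so recovery of losses from a low level was not tested.

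Imprinted regions were examined as markers of germ cell and somatic cell content. Regions methylated on the maternal allele lack methylation in male germ cells and carry it on the maternal allele in somatic cells, and paternally methylated regions carry it in male germ cells. Over the 11 of 16 maternal regions measured, the mean was 8.53% ± 3.26 (SD, n = 5) in control and 8.59% ± 0.701 in arsenic. The control levels were 16.3% ± 2.0 for Nnat, 13.9% ± 11.8 for Plagl1, 12.5% ± 6.89 for Peg13, 12.1% ± 5.64 for Nap1l5, 10.99% ± 6.48 for Mcts2, 7.95% ± 6.48 for Airn, 7.92% ± 5.06 for Zrsr1 and 6.69% ± 3.91 for Peg10. Nespas stood at 3.35% ± 6.02 in control, Grb10 at 2.14% ± 1.81 and Inpp5f at 0.0980% ± 0.219. In arsenic the levels of these 11, in the same order, were 13.0%, 5.78%, 12.4%, 11.3%, 15.2%, 8.80%, 7.63%, 10.3%, 5.39%, 3.39% and 1.27%. Of the paternal regions, that upstream of H19 stood at 95.2% ± 2.85 in control and 95.6% ± 2.17 in arsenic, and that upstream of Rasgrf1 at 73.5% ± 6.60 and 72.4% ± 7.18. The exact permutation p was 0.976 for the maternal and 0.905 for the paternal list, and 0 members of either passed, adjusted over the list alone or over all gene ends. Without Grb10 and Inpp5f, whose imprinted regions lie inside the gene, the maternal difference was -0.200 percentage points in place of 0.0572.

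Germ cell genes included meiotic and piRNA pathway genes whose promoters are methylated in somatic tissue, and genes of late spermatogenesis. Levels of these lists and of those below were taken at the gene end with more covered CpGs, which need not be the promoter. Members with few covered CpGs weigh equally in a mean, such as Tex19.1 (95.8% in control, 5 CpGs) and Piwil1 (89.8% in control, 5 CpGs). The 20 of 24 germline genes measured averaged 31.3% ± 1.58 (SD, n = 5) in control and 29.3% ± 2.21 in arsenic, with 13 members lower and 7 higher. Asz1, a piRNA pathway gene, stood at 27.3% ± 4.39 in control and 18.6% ± 7.02 in arsenic, the homeobox gene Rhox13 at 16.9% ± 15.7 and 3.04% ± 4.0, and Tex101, a germ cell surface protein gene, at 21.01% ± 2.31 and 17.9% ± 1.33. The 10 of 20 late spermatogenesis genes measured averaged 37.5% ± 1.09 in control and 35.6% ± 1.08 in arsenic, with 8 lower and 2 higher. Tnp1, a transition nuclear protein gene, stood at 21.1% ± 5.82 and 14.6% ± 7.70, the transcription factor gene Crem at 4.92% ± 3.99 and 2.06% ± 1.42, and the chaperone gene Hspa1l at 32.8% ± 9.25 and 28.4% ± 3.47. The exact permutation test gave p = 0.0476 for the late spermatogenesis list, which did not hold after adjustment over the 10 lists (adjusted p = 0.437). For the germline list the exact test gave p = 0.167, with an adjusted p of 0.556. Counts of members that passed were 0 in both, adjusted over the list alone and over all gene ends; 2 germline members and 0 late spermatogenesis members had an unadjusted p under 0.05 in the quasi-binomial model. At a coverage of at least 20 reads, the germline difference of -2.0 percentage points was 0.128.

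Somatic cell genes of the testis showed no difference beyond the spread between libraries. The 12 of 15 Sertoli cell genes measured, from the supporting cells of the tubule, averaged 7.99% ± 1.35 (SD, n = 5) in control and 7.03% ± 1.45 in arsenic. Within this list Clu stood at 6.47% ± 2.48 and 3.35% ± 1.38, Sox9 at 3.80% ± 3.32 and 1.58% ± 1.11, and Inhbb at 2.32% ± 1.53 and 0.839% ± 0.989. The 9 of 12 genes of Leydig cells, which make androgens, averaged 46.9% ± 1.19 and 47.2% ± 2.57. In that list Cyp17a1, a steroid hydroxylase gene, stood at 84.3% ± 4.52 and 88.3% ± 3.39, the luteinizing hormone receptor gene Lhcgr at 1.77% ± 3.09 and 8.01% ± 11.6, and Nr5a1 at 30.8% ± 7.67 and 27.3% ± 3.72. The 7 of 11 genes of peritubular, vascular and immune cells averaged 58.1% ± 2.16 and 59.3% ± 1.71, with Cnn1 at 30.2% ± 2.41 and 33.6% ± 4.70, Myh11 at 2.89% ± 2.57 and 5.13% ± 5.67, and Pdgfra at 2.66% ± 1.79 and 3.64% ± 3.36. The exact permutation test gave p = 0.310, 0.810 and 0.397 for the 3 lists in this order. Adjusted over the list alone, 0 members passed in each, and 3, 0 and 0 members had an unadjusted p under 0.05.

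Genes of the DNA methylation machinery and of methyl-group supply were examined because arsenic is detoxified by methylation. The 13 of 16 machinery genes measured averaged 6.75% ± 1.10 (SD, n = 5) in control and 7.10% ± 1.51 in arsenic. Mbd3, a subunit of a chromatin remodelling complex, stood at 12.1% ± 9.45 and 4.17% ± 3.95, the methylcytosine dioxygenase gene Tet3 at 4.77% ± 4.41 and 0.889% ± 1.48, and the DNA glycosylase gene Tdg at 0.213% ± 0.233 and 3.79% ± 4.81. The 17 of 21 one-carbon and arsenic metabolism genes averaged 15.7% ± 1.12 and 15.2% ± 0.707. Pemt, a phospholipid methyltransferase gene, stood at 0.274% ± 0.308 and 2.35% ± 2.46, Ahcy, which encodes the enzyme that clears S-adenosylhomocysteine, at 4.49% ± 2.72 and 1.74% ± 0.415, and the aquaporin gene Aqp9 at 90.5% ± 2.98 and 93.8% ± 1.74. As3mt, the arsenic methyltransferase gene, had no covered CpG in its window. The exact permutation test gave p = 0.730 and p = 0.460, and 0 members of either list passed, adjusted over the list alone or over all gene ends, with 3 and 2 members at an unadjusted p under 0.05. Without control libraries 4 and 5 the one-carbon difference of -0.515 percentage points was -0.0310.

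Genes of the oxidative stress response, which arsenic activates in exposed tissue, averaged 4.59% ± 1.21 (SD, n = 5) in control and 3.58% ± 0.403 in arsenic, over 18 of 24 measured. Of these, 12 stood lower in arsenic and 6 higher. Sod1, the cytosolic superoxide dismutase gene (chromosome 16, 90219762 to 90221762), stood at 6.49% ± 4.26 in control and 0.958% ± 1.06 in arsenic. The glutathione peroxidase gene Gpx1 stood at 12.9% ± 4.82 and 7.44% ± 4.46, and the metallothionein gene Mt1 at 7.13% ± 1.30 and 5.85% ± 0.915. The exact permutation test gave p = 0.0873 for the list, with an adjusted p of 0.437. In the quasi-binomial model 2 members had an unadjusted p under 0.05 and 0 passed, with Sod1 at an adjusted p of 0.0579 over the list alone and 0.568 over all gene ends. Control libraries 4 and 5 had the highest levels of this list, 4.87% and 6.49%, and without them the difference of -1.01 percentage points was -0.281.

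**Figure D3:**
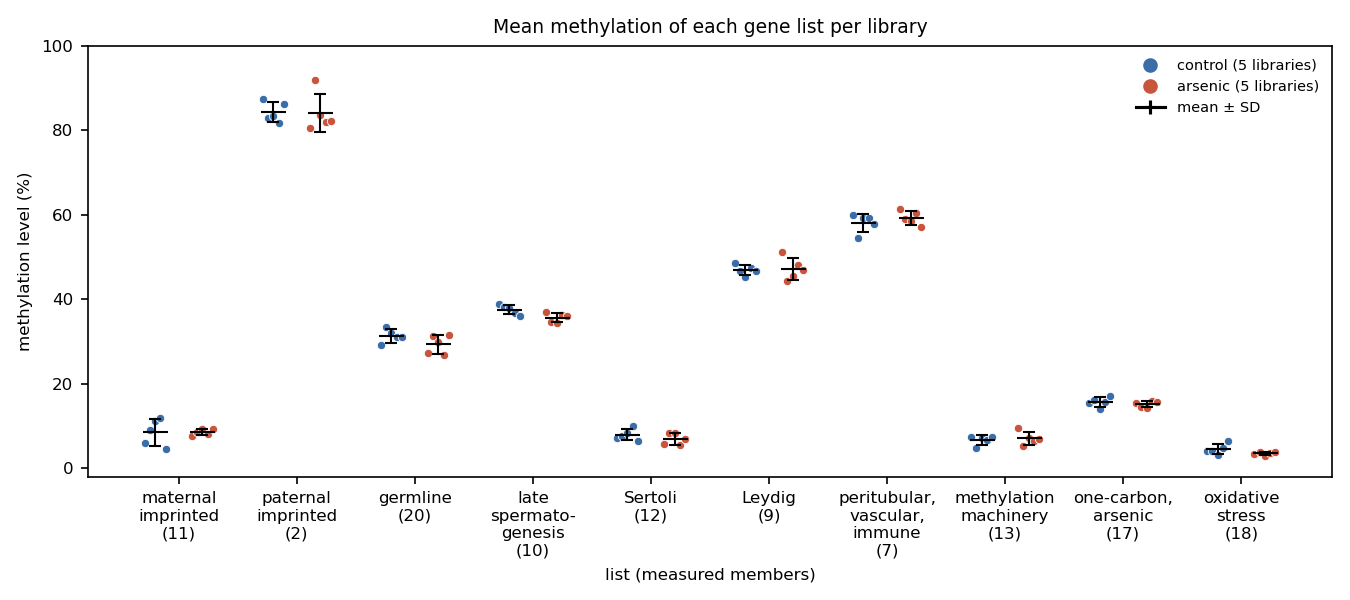
Mean methylation in percent (vertical axis) over the measured members of each of the 10 gene lists, in the 5 control and 5 arsenic libraries. Points are libraries, bars are the mean ± SD, and the number under each list is its measured members; the paternal imprinted regions average 84.3% in control and the maternal ones 8.53%.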

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

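Each group of 5 libraries was checked for a library lying far from the other 4 (a gap to its nearest neighbour above 0.71 of the group's range), over the depth measures, genomic classes, lists and named genes. Of 148 groups checked, 21 held such a library, where chance alone gives about 7.4. Many of these groups lie near 0%, where levels are skewed, so the excess was not read as a pattern. Arsenic library 5 stood above the rest of its group over all cytosines (53.8% against 53.2% to 53.3%), autosomes (53.7% against 53.1% to 53.3%) and intergenic CpGs (67.4% against 66.5% to 66.8%). Arsenic library 2 stood above its group over the paternally methylated regions (91.8% against 80.4% to 83.5%) and at Rasgrf1 within them (85.0% against 67.9% to 71.0%). Control library 2 stood below its group over the DNA methylation machinery (4.83% against 6.81% to 7.51%).

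Among maternally methylated regions, Nap1l5 stood at 22.2% in control library 3, against 8.98% to 10.2% in the other control libraries. Control library 4 was apart at Peg10 (13.3% against 3.61% to 6.24%) and at Nespas (14.0% against 0% to 1.99%). Inpp5f stood at 0.490% in control library 2 and at 0% in the other controls, and Grb10 at 10.6% in arsenic library 5, against 0.838% to 2.98%. In germ cell genes, Rhox13 stood at 10% in arsenic library 5, against 0% to 2.63%, and Tex101 at 15.6% in arsenic library 4, against 18.1% to 18.8%.

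Lhcgr, the luteinizing hormone receptor gene of Leydig cells, stood at 28.3% in arsenic library 1, against 0% to 5.71%, and at 7.14% in control library 1, against 0% to 1.69%. Arsenic library 1 was also apart at Tdg (12.2% against 0.663% to 3.39%). Arsenic library 2 was apart at Tet3 (3.53% against 0.133% to 0.440%) and at Inhbb (2.60% against 0.328% to 0.522%). Arsenic library 4 was apart at Myh11 (15.2% against 2% to 3.61%) and at Sod1 (2.79% against 0.190% to 0.859%). Mt1 stood at 7.44% in arsenic library 5, against 5.09% to 5.66%.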

How the results depend on the processing

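Counts of calls were 0 in every setting run except the binomial test with reads as replicates (82352 cytosines, 1986 tiles, 74 gene ends) and limma (1 tile and 1 gene end, both at Xlr5c, and 0 cytosines). The binomial test takes no spread between libraries into account by construction; the cause of limma's call was not tested. With the replicate number as a block (replicate block), counts stayed at 0 for cytosines, tiles and gene ends, and the mean methylation difference of -0.278 percentage points had an exact sign-flip p of 0.188, where 0.0625 is the smallest that 5 pairs allow. No pairing is known beyond the shared number. Deviations of same-numbered libraries correlated at -0.0126 to 0.0167. Control libraries 1, 2 and 4 correlated best with their own number, and control libraries 3 and 5 did not. Whether this exceeds chance was not tested. The difference in mean methylation ranged from -0.388 to -0.122 percentage points with 1 library left out, and was 0.0320 without control libraries 4 and 5 and -0.587 with cytosines weighted by reads.

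No list passed in any setting. A single list could not: adjusted over 10 lists, the smallest exact p of 0.00794 stays above 0.05 when only 1 list reaches it. With the replicate block the smallest p, 0.0625, lies above 0.05 before adjustment. Where a difference changed sign, the cause was not tested. For maternally methylated regions (0.0572) the values were -0.232 at a coverage of 20, -0.0816 with reads summed, -0.138 without control libraries 4 and 5, -0.200 without Grb10 and Inpp5f, and -0.952 to 0.920 with 1 library left out. Leaving out 1 library gave -2.28 to 0.563 for paternal regions, -0.624 to 1.05 for Leydig genes and -0.251 to 0.767 for the methylation machinery. Lists that kept their sign also moved by over 1.5 times: Sertoli genes from -0.958 to -0.434 without control library 4, peritubular, vascular and immune genes from 1.19 to 0.286 without control library 2, one-carbon genes from -0.515 to -0.132 without control library 5 and -0.900 without control library 3, and oxidative stress genes from -1.01 to -0.533 without control library 5. The germline list was 0.128 at a coverage of 20, Leydig genes -0.243 and one-carbon genes 0.0567 with 500 bp windows, and peritubular, vascular and immune genes -0.0371 with reads summed. Besides the changes of sign and of call counts, 212 values of the comparisons kept their direction and side of the threshold. Those that kept their sign but moved in size are among them. Of the values of named tiles and gene ends, 287 did so, and 18 passed the threshold, in the binomial test or limma. A coverage minimum of 5 was not run. In simulated data 9 of 100 differences of 30 percentage points at single cytosines were recovered. How much of this limit comes from depth, the number of libraries, the number of tests or the small share of changed cytosines was not separated.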

Other observations

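Tests chosen after the result they measure had been seen were those on splits of the libraries for tiles, on bisulfite conversion (mitochondrial cytosines, 5 low percentiles and a correction), on the side of control libraries 4 and 5 and leaving these 2 libraries out, with the splits of the 8 remaining libraries, on the 10 level classes and the share of somatic cells, and on a sequence variant and shared reads at Xlr5c. Tiles were grouped by their mean level over all 10 libraries. The 1975 tiles under 1% stood at 0.692% ± 0.0198 in control and 0.729% ± 0.0423 in arsenic (exact permutation p = 0.111), and the 65740 tiles above 90% at 93.6% ± 0.343 and 93.7% ± 0.256 (exact permutation p = 0.817). Tiles of 20 to 40% stood at 29.6% ± 0.886 in control and 27.7% ± 1.06 in arsenic (9422 tiles), and tiles of 10 to 20% at 16.0% ± 0.772 and 14.6% ± 0.944 (6422 tiles), with an exact permutation p of 0.0159 in each. The classes of 1 to 2%, 2 to 5%, 40 to 60%, 60 to 80% and 80 to 90% differed by -0.0661, -0.510, -0.799, -0.0707 and 0.391 percentage points. For these the exact permutation p was 0.0794 or more. Without control libraries 4 and 5 their differences were 0.0691, 0.0297, -0.534, 0.248 and 0.782. Tiles of 5 to 10% stood at 7.57% ± 1.01 and 6.52% ± 0.312 (4490 tiles, exact permutation p = 0.0397, adjusted p = 0.132). There control libraries 4 and 5 stood at 8.13% and 9.07%; the difference of -1.05 percentage points was -0.670 without control library 5 and -0.359 without both (exact permutation p = 0.179). In 9378 tiles with at least 20 CpGs and 500 reads in every library, the 1st, 2nd, 5th and 10th percentiles of the levels were higher in arsenic by 0.0467, 0.0319, 0.0297 and 0.0127 percentage points. The 25th was lower by 0.0650, and the exact permutation p was 0.0873 or more for all 5. Xlr4a, Xlr4b and Xlr4c, which neighbour Xlr5c on the X chromosome, stood at 14.9%, 15.9% and 16.2% at their ends in control and 20.9%, 15.2% and 18.1% in arsenic, with adjusted p in the quasi-binomial model of 0.885, 0.9984 and 0.931.

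Over the 15844 tiles of 10 to 40% the difference, arsenic minus control, was -1.70 percentage points, a relative change of -7.05%. The exact permutation p was 0.0159 for this set, which was put together after its 2 classes had been seen; adjusted over the 10 level classes it was 0.0794 for each of them, so chance could not be excluded. Higher methylation in control libraries 4 and 5 is argued against, since the difference was -1.82 without them (exact permutation p = 0.0536). A smaller share of somatic cells in the arsenic samples may account for the lower level. It stays open: the same relative change would be -0.601 percentage points in the maternally methylated regions, where the difference was 0.0572 with a 95% interval of -3.95 to 4.06, and an effect of arsenic was not tested apart from it.

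Of the 909 gene ends with an unadjusted p under 0.05, 72.5% were lower in arsenic. Of 100 splits of the 10 libraries 5 against 5, drawn at random and with the real one among them, 20 were as one-sided, with a highest other share of 80.6%, so chance could not be excluded. Less complete bisulfite conversion in the control libraries is argued against as a source of the median of -2.84 percentage points at the lower gene ends. These were picked by p and direction, which can inflate their median, and the median over all gene ends was -0.261 percentage points. Unconverted reads would raise all tiles. Yet in the 9378 tiles above the 10th percentile of the levels was 0.472% ± 0.0356 (SD, n = 5) in control and 0.485% ± 0.0393 in arsenic. A smaller shift stays open, also as a source of the median over all gene ends. Mitochondrial cytosines differed by -0.140 percentage points (exact permutation p = 0.413), and 1 of 5 low percentiles was higher in control. With libraries set to the same mitochondrial level, 64.7% of gene ends with an unadjusted p under 0.05 were lower. That correction cannot decide, since the mitochondrial level of 2.58% in control lay above this percentile. The 20 splits as one-sided were all among the 45 that keep control libraries 4 and 5 on the same side, and 0 of the 55 that part them reached the real share, so these 2 libraries are a candidate explanation. Without them 62.3% were lower, between the bounds used (under 60% and at least 65%), and 21 of 56 splits of the 8 remaining libraries were as one-sided.

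The end of Xlr5c was at 0% in every control library and between 23.1% and 42.6% in the arsenic libraries. In 38 of 100 splits some gene end had a p as small as its 3.41e-05, the lowest in another split being 9.34e-08, so chance could not be excluded. A single C-to-T variant in the control animals is argued against, since each of the 5 cytosines had methylated reads in every arsenic library, and such a variant would alter 1 of them. Reads shared with another copy of the family, of which the gene table lists 3 Xlr5 genes, could add methylated reads and stay open: the window's share of a library's reads did not differ beyond the spread (exact permutation p = 0.603), which excludes nothing. A strain difference on the X chromosome and an effect of arsenic were not tested.

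Counts from the models were set against the same 100 splits. The real counts of called cytosines, tiles and gene ends were 0, which 100 of 100 splits reach by definition, so these counts say nothing on chance; the highest in another split were 1, 1 and 0. An unadjusted p under 0.001 was found at 2842 cytosines, a number reached in 25 of 100 splits (highest other 3103), at 196 tiles, reached in 13 (highest other 223), and at 19 gene ends, reached in 34 (highest other 31). Chance was not excluded for these 3 numbers. With reads as replicates, the 82352 called cytosines were reached in 4 of 100 splits (highest other 82837) and the 1986 tiles in 2 (highest other 2010), shares under 0.05 before any adjustment over the counts compared. All 4 of the cytosine splits were among the 45 that keep control libraries 4 and 5 on the same side, as the real one does, and 0 among the 55 that part them. Among those 45, a restriction chosen after seeing the data, the share is not under 0.05, so chance was not excluded for the cytosine count. For tiles, 1 of the 45 reached the count, the real split itself, and 1 of the 55 that part them. The tile share thus stayed under 0.05 among the 45, still before any adjustment over the counts compared. The 74 gene ends were reached in 10 splits (highest other 87). The median of the other splits was 78953 cytosines, 1770 tiles and 64 gene ends, so that test called nearly as many features between arbitrary groups of these libraries. In the real grouping 1987 tiles and 74 gene ends differed by at least 10 percentage points, and the test called 1986 and 74. Its tile and gene end counts thus mainly count the features past that minimum.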
